A study of Drosophila melanogaster with 4 samples.

How the data were processed

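Chromatin immunoprecipitation sequencing (ChIP-seq) was done on Drosophila melanogaster larvae at the wandering L3 stage. The flies carried a transgene of the Abd-B genomic region in which GFP, a green fluorescent tag, had been placed at the end of the coding sequence. Abd-B is the posterior Hox transcription factor of the bithorax complex. Per the labels, a rabbit polyclonal antibody against GFP was used for 2 ChIP libraries, and 2 libraries are of input DNA. Groups were taken from the sample titles. The series title also speaks of a mock, and the titles of all libraries, input included, carry the term vMock. Which libraries the peak caller took as its control is not given in the sources used here, and the collection protocol in the labels names another fly stock than the strain label.

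The processed data analysed here are 1 peak list for the whole series. Per the file headers it is a GFF version 3 table on FlyBase release 5, and its source field names MACS. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the genome build BDGP5, without parameters for any of them. Each deposited row gives the authors' peak position and 1 score from the authors' peak caller, with no scale named. That score was used only to describe, rank and filter peaks within the list. The deposited peak positions, the other values used here, were taken as the authors gave them, except that the lowest start in the file is 0, so starts were read as counting from 0 and 1 was added. Whether the authors pooled both ChIP replicates before calling, or combined separate calls, is not given in the sources used here. The list carries no value per library. No replicate error, no library size and no fold over input can therefore be computed, the depth is unknown, and no counting interval is given. All tests below describe how the peaks of this 1 list are distributed. Their p-values treat peaks as the unit and say nothing about the spread between larval collections.

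Peaks were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Medians carry 95% order-statistic intervals that take peaks as independent. Peaks per sequence were compared with 100000 random draws in proportion to sequence extent, two-sided, with Benjamini-Hochberg adjustment over the sequences tested. These draws place each peak independently and make no allowance for clustering. No release 5 genome was used here, so the extent of a sequence was the end of its last peak. Clustering was the share of peaks on the arms 2L, 2R, 3L, 3R, X and 4 that had another peak within 10 kb. It was compared with 10000 random placements of the same peaks, without overlap, within each arm (two-sided). P-values from random draws and placements are given as permutation p. Counts in windows of 1 Mb were set against the 95th percentile of the fullest window in 10000 placements per arm. A stretch was a run of peaks whose gaps were all at most 5 kb. The longest run of each arm was tested one-sided against 10000 placements and, separately, against 10000 shuffles of the arm's own gaps. The analyses of windows and stretches were chosen after the peak positions had been seen. Score and width were compared by Spearman's correlation across peaks with 100000 permutations, and medians between sequence classes with 10000 permutations (two-sided).

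The tests of arms, clustering and longest runs were tried on simulated data. Each simulation started from 2656 peaks as on the arms, but drawn at random and so not clustered like the real ones. Fewer draws were used than in the analysis, and the other tests were not tried. A planted 1.3-fold excess on 2R was called in 97 of 100 simulations, and in 0 of 100 without it. Random placement was called clustered in 3 of 100 simulations. A planted run of 40 peaks every 2 kb on 3R, put in place of the random peaks there, was called in 100 of 100 against either null. Without it, a run was called in 3 of 100 against random placement, and shuffled gaps were not tried.

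Before the data were examined, 22 gene lists and 13 motifs had been fixed, together with tests of peak location relative to genes, of the bithorax complex and of motif content. None of these was run. They need a release 5 genome or annotation, and the gene table at hand is on release 6. Coordinates were not converted. By the rule fixed in advance for that case, peaks are named by position: the 10 with the highest scores and the 3 widest. Peaks named beyond these were chosen after their values were seen. Alternatives were the 1474 and the 737 highest-scoring peaks, the arms alone, merging of peaks under 1 kb apart, other distances, other extents, and removal of the dense stretches.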

Results

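The deposited list held 2949 peaks of Abd-B-GFP in L3 larvae, for a series of 2 ChIP libraries and 2 input libraries. Of these, 2656 (90.1%) lay on the chromosome arms 2L, 2R, 3L, 3R, X and 4. The unplaced sequences U and Uextra, which collect contigs not assigned to a chromosome, held 262 peaks. The heterochromatic sequences 2RHet, 3LHet and 3RHet held 29 peaks, and the mitochondrial genome held 2. The list has 1 value per peak and none per library, so no measurement below has a replicate error, depth is unknown, and no region can be called unbound. All positions are on FlyBase release 5.

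Peaks were narrow. The median width was 346 bp (95% interval 340 to 356), with quartiles at 261 and 488 bp, and the smallest width, 200 bp, was shared by 57 peaks. The closest neighbours were 52 bp apart and no peaks overlapped. Peaks on the arms covered 0.925% of their extent. The authors' score had a median of 14.2 (95% interval 13.8 to 14.6) and ranged from 6.2 to 657.

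The highest scores of the list lay outside the assembled arms. A peak over positions 1 to 15004 of the mitochondrial genome had the highest score, 657. It was followed by a peak on U from 5288350 to 5303526, with a score of 649. These were also the only peaks wider than 10 kb, at 15004 and 15177 bp. Of the 10 highest-scoring peaks, 6 lay on U, Uextra or the mitochondrial genome. The other U and Uextra peaks among them started at 4022428 on U (score 274), 7542909 on U (score 271), 26549744 on Uextra (score 251) and 7729914 on U (score 176).

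On the arms, the strongest peak lay on 3R from 16603790 to 16604703, with a score of 177. The next was a broad peak of 2991 bp on 3R from 12758024 to 12761014, with a score of 173. A peak on 3R from 8889662 to 8890341 had a score of 166, and one on 3L from 18752114 to 18752836 had a score of 156. These 4 completed the 10 highest scores of the list. Chosen after their values were seen, the next on the arms were on 4 from 1322102 to 1323007 (score 155), on X from 8189275 to 8190250 (score 146) and on 2R from 10345442 to 10346037 (score 138). Of the 25 peaks of the list with a score above 100, 13 lay on the arms. The third widest peak of the list lay on X from 1504022 to 1509086, 5065 bp wide, with a score of 65.8.

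The chromosome arms differed in how many peaks they carried for their extent. 2R and 3R held the most, with 25.1 and 25.0 peaks per Mb, and 2L held fewer, with 17.2 peaks per Mb. Among the arms alone, 2L had 0.78 times the number expected from its extent (393 peaks, adjusted permutation p = 1.2e-04 against random placement). 2R had 1.13 times the expected number (530 peaks, adjusted permutation p = 0.0045) and 3R also 1.13 times (694 peaks, adjusted permutation p = 0.0011). 3L, with 539 peaks, X, with 480, and 4, with 20, did not differ detectably from expectation (adjusted permutation p = 0.93, 0.52 and 0.11). The excess on 3R did not pass the threshold once the dense stretches described below were left out (1.07 times, adjusted permutation p = 0.09). Among the 1474 highest-scoring peaks of the list only 2L passed it, and among the 737 highest-scoring, of which 541 lay on the arms, no arm did. The ratio on 4 turned with the setting. It was 0.67 times as deposited, 0.47 times with peaks under 1 kb apart merged (adjusted permutation p = 0.0089), and 1.31 and 1.97 times among the 1474 and the 737 highest-scoring peaks (adjusted permutation p = 0.42 and 0.25).

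With all sequences that held a peak in the comparison, 9 of 12 departed from expectation. A sequence without a peak had no extent here and could not enter. 2R, 3R, 3L and X held more peaks than expected, at 1.42, 1.41, 1.25 and 1.21 times, each with an adjusted permutation p of 2.7e-05. U held 0.23 times and Uextra 0.43 times the expected number. 2RHet held 0.26 times, 3LHet 0.13 times and 3RHet 0.21 times, all with an adjusted permutation p of 2.7e-05. Extents count every base, with no correction for unknown bases or for sequence where reads cannot be placed. The ratios, also those above expectation, therefore do not separate peak density from the amount of usable sequence. The p-values here, too, come from draws that ignore clustering and can be too small. Uextra changed side among the 737 highest-scoring peaks, with 1.23 times the expected number (adjusted permutation p = 0.02), while U stayed below it at 0.52 times (adjusted permutation p = 0.0048). 2RHet and 3RHet no longer passed the threshold there (0.48 and 0.37 times, adjusted permutation p = 0.078 and 0.072). Among the 737 highest-scoring peaks 2R, 3R, 3L and X did not pass the threshold (adjusted permutation p = 0.46, 0.99, 0.56 and 0.27). There 3R and 3L were no longer above expectation (0.994 and 0.936 times). The excess on 3L did not pass it among the 1474 highest-scoring either (1.11 times, adjusted permutation p = 0.12). The direction for 3L and X also depended on the reference, since both were slightly below expectation among the arms alone (0.996 and 0.967 times). 2L, 4 and the mitochondrial genome did not pass the threshold here (adjusted permutation p = 0.62, 0.56 and 0.11). The 2 mitochondrial peaks passed it among the 1474 and the 737 highest-scoring peaks (adjusted permutation p = 0.033 and 0.02).

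Although few in number, peaks outside the arms scored higher. The median score was 30.5 on U and Uextra against 13.5 on the arms, a difference of 17.0 (adjusted permutation p = 4e-04). It was 21.7 on the Het sequences, 8.16 above the arms (adjusted permutation p = 0.0018). Widths on U and Uextra did not differ detectably from those on the arms, with medians of 364.5 and 343 bp (adjusted permutation p = 0.13). Het peaks were wider, with a median of 520 bp (adjusted permutation p = 0.0011). The 20 peaks of chromosome 4, the small dot chromosome, had a median score of 25.7 against 13.4 on the other arms (adjusted permutation p = 4e-04) and a median width of 497 against 342 bp (adjusted permutation p = 0.0059). On X the median score was 14.2 against 13.3 on the other arms, which did not pass the threshold (adjusted permutation p = 0.053).

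Higher-scoring peaks were wider. Across all 2949 peaks Spearman's rho of score and width was 0.57 (permutation p = 1e-05, the smallest that 100000 permutations can give). It was 0.59 on the arms and 0.47 on U, Uextra and the Het sequences, each with an adjusted permutation p of 1e-05 over 3 correlations. It was lower within the 1474 and the 737 highest-scoring peaks, at 0.36 and 0.24 (permutation p = 1e-05 in both). These sets were cut on the score itself, which narrows its range and can alone lower rho. Score and width also come from the same peak calls, so they are not separate measurements. These are correlations across peaks of 1 list, and peaks are not replicates.

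**Figure D1:**
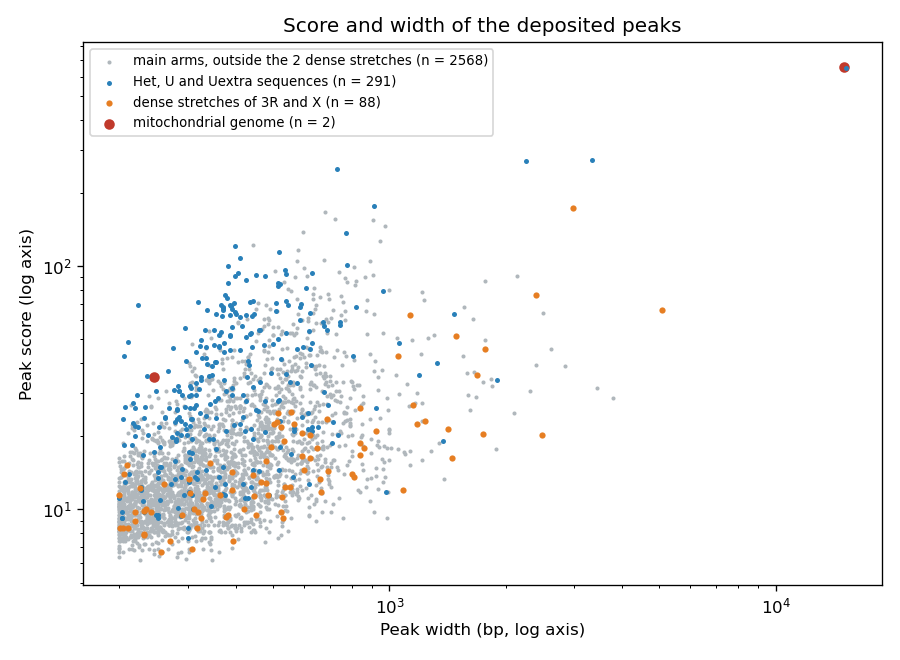
Score against width of each deposited peak, both on log axes, coloured by the sequence class or stretch it lies in. Peaks of U and Uextra had a median score of 30.5 against 13.5 on the arms, and the 2 peaks wider than 10 kb, on the mitochondrial genome and on U, nearly coincide at the top right.

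Peaks on the arms lay closer together than random placement gives. Of the 2656 arm peaks, 61.3% had another peak within 10 kb, against 36.4% in random placements (95% range 34.2 to 38.6, permutation p = 2e-04, the smallest that 10000 placements can give two-sided). Without the 2 dense stretches described next, the share was 59.9% against 35.4%. Of 123 windows of 1 Mb, 11 held more peaks than the 95th percentile of the fullest window in random placements. The fullest were on X from 1 to 2 Mb with 90 peaks, on 3R from 12 to 13 Mb with 89 and on 3R from 0 to 1 Mb with 61. On 2R the windows from 2 to 3 and from 3 to 4 Mb held 47 and 48 peaks.

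**Figure D2:**
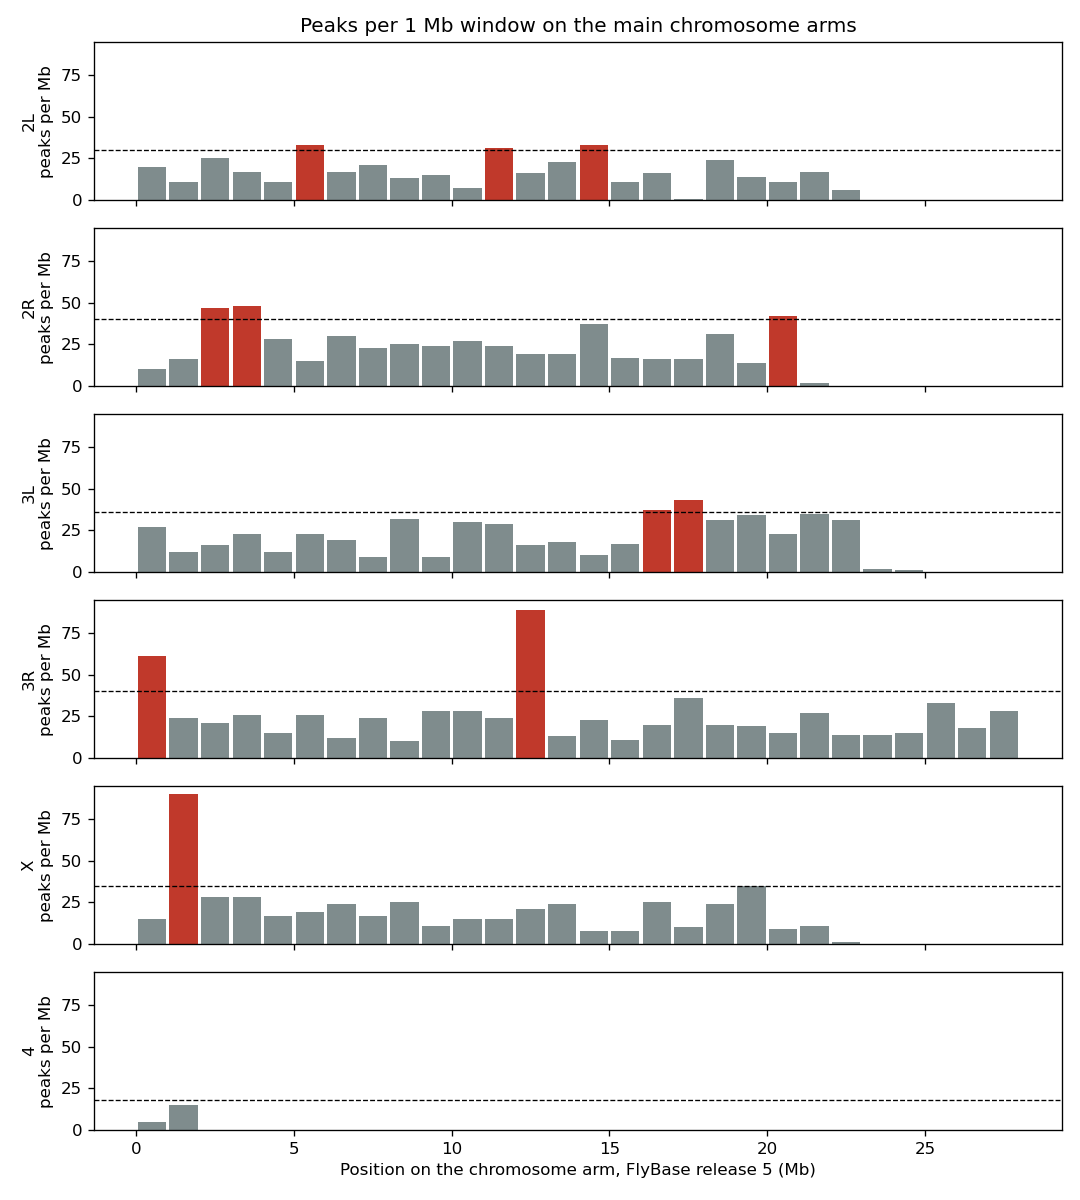
Number of peaks in each 1 Mb window along 6 chromosome arms. Dashed lines mark the 95th percentile of the fullest window in random placements, and the windows above it are red, with 90 peaks on X and 89 on 3R as the fullest.

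Of the 89 peaks in the fullest window of 3R, 55 formed a single stretch. From 12755332 to 12848297, a length of 93.0 kb, 55 peaks followed each other with no gap above 3.59 kb, which is 7.93% of the peaks of 3R. They covered 35.9% of the stretch, against 0.875% of the arms outside both dense stretches. The next peak lay 33.6 kb away on the right side and 5.63 kb away on the left. Its strongest peak was the broad one from 12758024 to 12761014, and the median score was 14.3 (95% interval 11.7 to 17.8), against 13.5 (13.2 to 13.8) on the rest of the arms. In random placements of the 3R peaks the longest run never exceeded 9 peaks, and in shuffles of its gaps it never exceeded 15 (adjusted permutation p = 1.5e-04 and 3e-04). The longest run on 3R was 26 peaks with peaks under 1 kb apart merged and 13 among the 1474 highest-scoring peaks. Among the 737 highest-scoring it was 3 peaks, which did not pass the threshold (permutation p = 0.056).

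A second stretch lay on X from 1454969 to 1521744. It held 33 peaks in 66.8 kb, covered 42.6% of that length and had no gap above 4.76 kb. Its strongest peak ran from 1471112 to 1473512 with a score of 75.7, and it also held the widest peak of the arms. Its median score was 12.4 (95% interval 10.0 to 16.3). A further run of 9 peaks from 1529751 to 1543303 followed after a gap of 8.01 kb. The longest run never exceeded 8 peaks in random placements of the X peaks and 15 in shuffles of their gaps (adjusted permutation p = 1.5e-04 and 3e-04). The longest run anywhere on X was 15 peaks with peaks under 1 kb apart merged. It was 7 and 4 among the 1474 and the 737 highest-scoring peaks. Among the 1474 highest-scoring peaks, a run of 7 lay from 1529751 to 1543303, outside the stretch. The longest run on X therefore need not lie in the stretch. The third longest stretch of the arms, on 3L from 17550319 to 17576382, held 12 peaks (adjusted permutation p = 1.5e-04 against random placement and 0.0034 against shuffled gaps). The longest runs of 2L, 2R and 4 held 7 peaks each, more than in random placements (adjusted permutation p = 4.8e-04, 0.0014 and 1.5e-04), but not more than in shuffled gaps (adjusted permutation p = 0.14, 0.25 and 0.11).

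**Figure D3:**
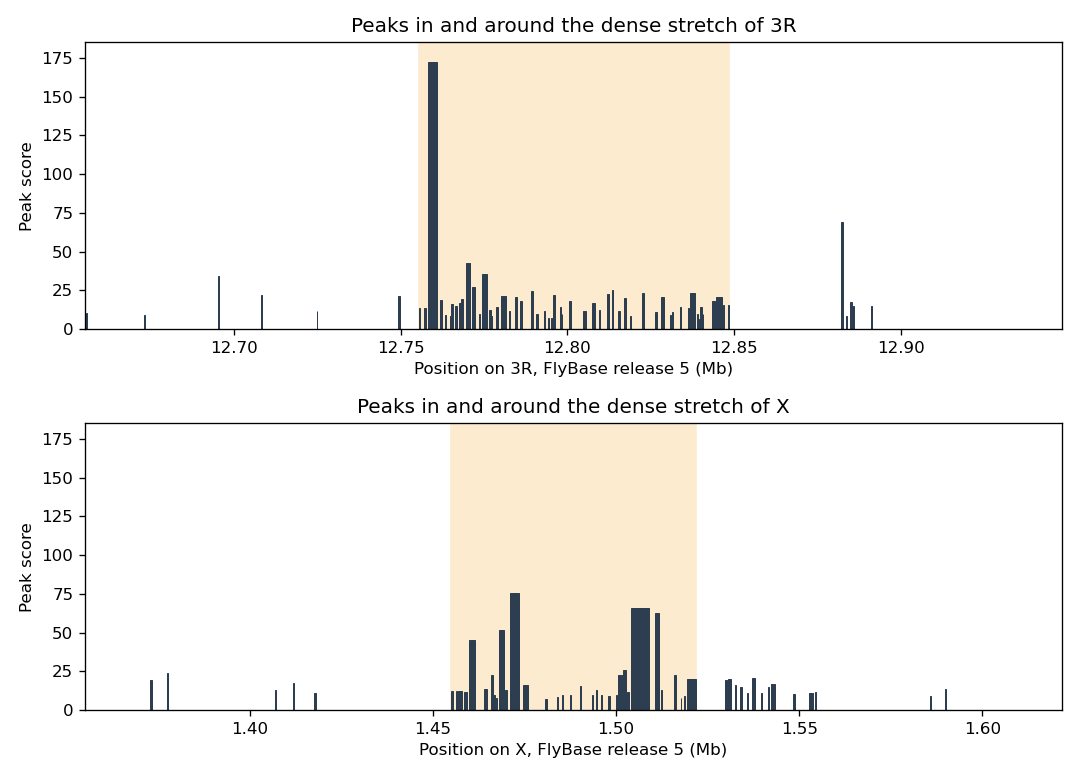
Peaks in and within 100 kb of the dense stretches of 3R and X (shaded), each drawn to scale as a box from its start to its end with its score as height. The 3R stretch holds 1 peak of score 173 and many lower ones, and the X stretch holds several broad peaks of up to 75.7.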

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

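No paired analysis was possible because the peak list holds no value per library, and none could be left out. Taking only the 1474 or the 737 highest-scoring peaks gave median widths of 446 and 510 bp and median scores of 22.4 and 34.0. The median score was 13.5 on the arms alone, and merging peaks under 1 kb apart gave a median width of 366 bp and a median score of 14.8. Sequences departing from extent were 9, then 4 with the 737 highest-scoring peaks, 3 among the arms alone and 4 there with merged peaks. Outside the 9 were 2L, 4 and the mitochondrial genome. Of the 3 arms, 1 departed with the 1474 and 0 with the 737 highest-scoring peaks, where fewer peaks were tested. Against all sequences, the ratio on 3L fell below expectation with the 737 highest-scoring peaks (0.936) and among the arms alone (0.996), that on X among the arms alone (0.967) and with peaks merged as well (0.941), and that on 3R with the 737 highest-scoring peaks (0.994). Among the arms alone 3R fell below it with the 737 highest-scoring peaks (0.973). Against all sequences Uextra rose above it with the same peaks (1.23). Over all sequences taken singly, 6 of 102 alternatives brought a ratio past the threshold and 17 ended a call. In 17 the ratio changed side of expectation, 7 of them ratios that had passed the threshold (given above) and 10 that had not. Of these only Uextra passed it after the change, and the cause was not tested. The longest runs anywhere on the arm changed in length from 55 peaks on 3R and 33 on X. They were 21 and 11 with gaps up to 2 kb, 56 and 45 with gaps up to 10 kb, and 26 and 15 with merged peaks. They were 13 and 7 with the 1474 and 3 and 4 with the 737 highest-scoring peaks. Of these only the 3 peaks on 3R did not pass the threshold (permutation p = 0.056). Clustering kept its direction and call in each of 6 alternatives (permutation p = 2e-04 in each), from 35.1% against 8.69% (737 highest-scoring peaks) to 74.8% against 59.4% (within 20 kb). The correlation of score and width and the higher score on U and Uextra kept theirs in each alternative run, but rho ranged from 0.24 to 0.59. Not run, for want of a release 5 genome or another score, were placement near gene starts, lengths without unknown bases, and the alternatives for genes, motifs and the bithorax complex. Alternatives on the dense stretches, and the arms with merged peaks, were chosen after seeing the data.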

Other observations

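All tests in this part were chosen after the peak list had been seen. The peaks of the dense stretches were wide for their score. In the 3R stretch 46 of 55 peaks were wider than the median of the 25 arm peaks closest in score outside both stretches, with a median log2 width ratio of 0.41 (95% bootstrap interval 0.29 to 0.66, permutation p = 2e-04). In the X stretch it was 28 of 33 peaks, with a median log2 ratio of 0.79 (0.37 to 1.02, permutation p = 2e-04). Intervals and p-values take neighbouring peaks of 1 region as independent. Smaller runs were not matched for score, so the trait may not be particular to these stretches. The run of 9 peaks on X had a median width of 583 bp (median score 15.9). A run of 8 peaks on X from 3634970 had 338.5 bp (median score 19.1). The median was 341 bp on the arms outside both stretches.

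A hypothesis for the 3R stretch is that the ChIP chromatin held extra copies of this segment relative to the control. The strain carries a transgene of the Abd-B genomic region, Abd-B lies on 3R, and a copy difference may give many neighbouring peaks that are broad for their score. The width ratio of 0.409 on the log2 scale has the sign this needs, but broad enrichment of other origin would widen peaks too. Input of the same strain would cancel a copy difference, and the titles of both input libraries name Abd-B-GFP. The hypothesis therefore needs a control other than these inputs, and which control was used is not given. Binding of the tagged protein at many sites along the stretch was not tested and stays open. Scores in the stretch reached from 6.7 to 173. Whether the stretch covers Abd-B itself was not checked, since no release 5 annotation was used here.

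The X stretch showed the same sign, with a width ratio of 0.787 on the log2 scale, although the labels name no transgene of an X segment. The difference between the stretches was not tested. Extra copies of an X segment, binding at many sites, and broad enrichment of other origin over this region all stay open, and the test on widths does not separate them.

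The mitochondrial peaks covered 79.6% of that genome up to its last peak. The main one was 11.7 times as wide as the 99th percentile of arm peaks outside both dense stretches. Such a width would be unusual for local binding of the tagged protein. But this peak was named for its score and width, so the comparison cannot exclude binding. A different amount of mitochondrial DNA in ChIP and control could give such a peak, but with no value per library this could not be tested. The peak on U had nearly the same width (1.15% more) and score (-1.32% relative to the mitochondrial peak), so mitochondrial sequence placed on U is a candidate source, but with no sequence to compare this cannot be told apart from a chance likeness.

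Scores recurred: 8.91 occurred 28 times, and 1944 scores from 8 to 20 took 768 distinct values. They are given to 0.01, so rounding alone makes some values recur, and how many was not tested. A hypothesis is that the score is the negative log10 of a Poisson tail probability for whole read numbers over 1 background level, perhaps after a correction. The best of the ladders of such values held 31.8% of these scores within 0.01, against at most 20.2% in 100 sets in which each distinct score was moved as a whole, so that values still recurred. The best evenly spaced ladder held 19.4%. Most scores lie off the ladder, so no background level or fold is read from it.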
